A study of Mus musculus with 12 samples.

How the data were processed

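RNA of B16F10 mouse melanoma cells was sequenced in 12 libraries, 3 for each of 4 groups that crossed the IRF7 form (wild type or C435A) with IFNα or control, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols the libraries were poly(A)-selected and stranded by the dUTP method, carried molecular identifiers in their adapters and were read as pairs. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2, edgeR and the build GRCm38, without the role or order of each. How fragments were counted, whether identifiers were used to remove duplicates, whether strand was used and which annotation applied are not given in the sources used here. Without stated strand use, genes that overlap on opposite strands cannot be told apart.

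The authors deposited 1 table of 27503 genes with a count and an FPKM per library. The deposited counts are whole numbers not scaled for depth, per the file headers, with totals from 60511573 (mutant IFNα 3) to 75927461 (wild-type IFNα 1). Of the values from 1 to 30, 33.6% were multiples of 4, where 23.3% of the whole numbers in that range are, so a count is not 1 fragment and its counting error is larger than its square root. Over 6318 genes with a mean count of at least 1000, the SD of the log2 ratio between libraries of 1 group was 0.228 to 0.431 in 12 pairs. Counting error would give at most 0.043, or 0.086 at 4 counts per fragment, so the spread between libraries sets the precision and no pair was 1 library held under 2 names. The deposited FPKM were scaled by the authors for transcript length and library size, per the file headers. Of the gene identifiers 95.1% are in the GRCm38 annotation used here, but only 2% of gene starts outside the mitochondrion and chromosome Y are equal, so coordinates are given as deposited and were not converted. The table repeats 30 gene symbols on more than 1 row, and rows were kept apart by identifier.

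Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, its default filter on low counts (17590 genes kept) and the quasi-likelihood test. A single fit over all 12 libraries had 4 group means and no covariate, so that all groups share an estimate of the spread (common biological coefficient of variation 28.9%). The 5 comparisons were IFNα against control in each line, mutant against wild type without and with IFNα, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05, and a second count asked for at least 2-fold. The design, written before the data were examined, named limma on FPKM unless the table also held counts, in which case edgeR was to take its place. It did, so limma-trend (limma 3.58.1) on log2(FPKM + 1), over 10094 genes with FPKM of at least 1 in at least 3 libraries, became an alternative. Fold changes from limma are on that scale and understate changes of low genes.

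Before the data were examined, 27 gene lists were written for interferon signaling, antigen presentation, melanoma state, metabolism, stress and other cell types. The 24 lists with at least 5 members past the FPKM filter were tested with camera on log2(FPKM + 1), at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Only members past that filter entered camera, while counts of members and medians cover all members tested in edgeR, except that medians in unscaled FPKM and after quantile normalization cover the members past the filter. A list is said to have moved up or down where this test passed. None of the list calls held with an estimated correlation.

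Genes were named by a rule written before the data were examined. It took up to 10 genes with the largest increase and 10 with the largest decrease among those past the threshold, with a mean FPKM of at least 5 in the higher group and no overlap between libraries, leaving out predicted genes and pseudogenes. It added 23 genes to be reported whatever their result, of which 1 is not reported here, and up to 4 members of each list with the smallest adjusted p. Genes outside this rule are marked as chosen after their values were seen.

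The code was tested on simulated counts with the means and library sizes of the real data, 200 genes being changed in each comparison. Of the 4-fold changes it recovered 71.2% for IFNα in the wild type, 63.6% for IFNα in the mutant, 71.2% for the mutant without IFNα, 77.3% with IFNα and 45.5% in the interaction. Of the 2-fold changes it recovered 37.3%, 41.8%, 41.8%, 53.7% and 9%, and of the 1.5-fold changes 14.9%, 13.4%, 6%, 26.9% and 0%. False calls numbered 5, 4, 1, 10 and 2 among 17070, 17060, 17075, 17066 and 17070 genes.

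Alternatives set beforehand were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals as scaling, no filter on low counts, an FPKM minimum of 5, robust estimation, limma with and without a variance trend, with a pseudocount of 0.1 and with quantile normalization. Others were the replicate number as a block, only the groups compared, and leaving out each library in turn. After the data were seen, a term for libraries with transcripts of other tissues, only those libraries, counts divided by 4, an FPKM minimum of 1 in edgeR, leaving out both libraries with the largest TMM factors, list tests without each library, and list tests after a loess trend of each library with transcript length was removed were added. Transcript length was taken from the ratio of count to FPKM. Shifts of whole chromosomes were taken over 12438 genes with an average above 1 CPM on the autosomes and X. The sources used here name no batch. Sequence variants, including the codon of the substitution, and splice forms were not analysed here.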

Results

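RNA was sequenced from B16F10 cells, a transplantable mouse melanoma line, that carried either wild-type IRF7 or its C435A form, with and without interferon alpha (IFNα). IRF7 is a transcription factor that drives type I interferon genes, and C435A replaces a cysteine of the protein with alanine. The series title ties IRF7 to S-nitrosylation, the attachment of nitric oxide to cysteines, and to NOS1, the neuronal nitric oxide synthase. The 4 groups (wild-type control, wild-type IFNα, mutant control and mutant IFNα) held 3 libraries each. The deposited table gave counts and FPKM for 27503 genes. Library totals, 60511573 to 75927461 counts, are not numbers of sequenced fragments, as multiples of 4 were in excess. The labels name no separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 3 libraries per group). Where a library left out or a term ended a call, the values given are those of the fits concerned, or the range over all 12 fits that each left out 1 library. Gene lists were tested with camera on the members past an FPKM filter, whereas their counts and medians cover every member tested in edgeR. Medians in unscaled FPKM or after quantile normalization are over the members camera used. For the collagens, chemokines, leukocyte markers and MHC class II genes camera used 16 of 32, 18 of 32, 13 of 22 and 6 of 13. List tests with the trend of each library with transcript length removed were chosen after the data were seen. Levels are FPKM as mean ± SD over the same 3 libraries. Positions are those of the deposited table, whose gene starts differ from those of GRCm38, the build named in the submitters' processing notes.

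Transcripts of other tissues were present in 8 of the 12 libraries. The sum of 7 lung genes lay between 45.2 and 69.4 CPM (counts scaled to the library total after TMM adjustment) in all wild-type IFNα libraries, all mutant control libraries, wild-type control 1 and mutant IFNα 3. In wild-type control 2 and 3 and mutant IFNα 1 and 2 the sum was at most 0.229. The lung genes, among them Sftpc and Scgb1a1 of the surfactant-producing and secretory cells, were chosen after their values were seen. Of the epithelial and the fibroblast and endothelial markers set beforehand, 17 and 20 were tested. In each comparison 0 of them passed with edgeR, DESeq2 or limma, with at most 2 and 6 at an unadjusted p under 0.05, but most lay on the side of the lung transcripts. Of the 17 epithelial values 15 were positive with IFNα in the wild type, 2 with IFNα in the mutant, 16 in the mutant controls, 3 in the mutant with IFNα and 1 in the interaction, at medians of 1.59, −0.69, 1.37, −0.67 and −2.28. Of the 20 fibroblast and endothelial values 20, 3, 18, 4 and 2 were positive, at medians of 0.85, −0.43, 0.98, −0.40 and −1.29. Over the few members past the FPKM filter the medians in unscaled FPKM were 0.05, 0.13, −0.13, −0.04 and 0.10, so that the second, the third and the fifth turned. After quantile normalization the first was 0.07 and the fourth turned. The edgeR values of both lists are fitted values of genes near 0 in many libraries. Mutant IFNα 3 stood apart from its replicates, with an SD of the log2 ratio to them of 0.43 and 0.431 over 6318 genes, against 0.271 between those. On the second principal component it lay at 86.8 against 23.1 and 21.6. The first, where it lay at −68.8 against 45 and 47.3, went with the lung transcripts. Every library that held them was negative on it, also wild-type control 1, at −10.7 against 54.7 and 53 in its replicates.

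**Figure D1:**
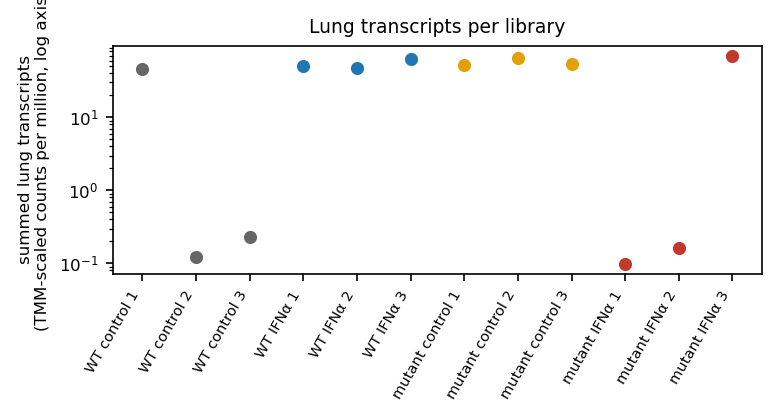
Summed CPM of 7 lung genes (log axis) in each of the 12 libraries, colored by group. In 8 libraries the sum lies between 45.2 and 69.4, and in wild-type control 2 and 3 and mutant IFNα 1 and 2 it is at most 0.229.

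Irf7 (ENSMUSG00000025498, chromosome 7, 140842619 to 140846394) was measured in every library. Its FPKM was 11.6, 12.8 and 12.5 in the wild-type controls and 8.84, 9.87 and 8.45 in wild-type IFNα. In the mutant it was 4.99, 4.44 and 5.2 in the controls and 4.63, 4.69 and 7.23 with IFNα. Irf7 fell by 1.23 ± 0.169 on the log2 scale in mutant against wild-type controls (adjusted p = 0.0057, lower in 3 of 3 libraries). Without mutant control 2 the call was lost, at −1.17. With IFNα the difference of −0.62 ± 0.167 did not pass in edgeR (adjusted p = 0.113) and passed in DESeq2, at −0.61, and in edgeR without mutant IFNα 3, at −0.88. The log2 fold change with IFNα was −0.45 ± 0.166 in the wild type (adjusted p = 0.798) and 0.16 ± 0.167 in the mutant (adjusted p = 0.791), neither past the threshold. A count per gene does not show the codon that differs between the lines. Nos1 (chromosome 5, 117919097 to 118092429) had 135 counts over all libraries, at most 26 in any of them, and Nos2, the inducible synthase, had 37. Nos3, the endothelial synthase, lay at 0.617 ± 0.12 FPKM in the wild-type controls and passed in none of the 5 comparisons (smallest adjusted p = 0.962). In the list of nitric oxide synthesis and S-nitrosothiol handling 0 of 26 genes passed in each of the 5 comparisons. With IFNα in the wild type and in the mutant, in the mutant without and with IFNα, and in the interaction, 4, 3, 3, 5 and 1 of them had an unadjusted p under 0.05, DESeq2 called 1, 0, 2, 1 and 0, and limma called 0. Adjusted over the list alone 1 was lower with IFNα in the wild type, 1 was higher and 1 lower in the mutant controls, and 0 passed elsewhere. Its smallest camera adjusted p was 0.488, and its median, mean and test differed in sign with IFNα in the wild type, in the mutant controls and in the interaction.

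IFNα treatment of wild-type cells shows the response without the substitution. IFNα lowered Id1 (chromosome 2, 152578171 to 152579330) and Id3 (chromosome 4, 135870808 to 135872703), inhibitors of helix-loop-helix transcription factors. Id1 went from 40.1 ± 3 to 17.9 ± 1.5 FPKM, a change of −1.18 ± 0.124 (adjusted p = 0.00316). Id3 went from 155 ± 22.4 to 77.3 ± 3.41 FPKM, a change of −1.01 ± 0.121 (adjusted p = 0.00643). Irf1 (chromosome 11, 53660841 to 53668149), an interferon-induced transcription factor, rose from 8.28 ± 0.755 to 13.7 ± 1.92 FPKM, by 0.71 ± 0.0984 (adjusted p = 0.0202). For these genes every IFNα library lay beyond every control library. The only other gene past the threshold, Col9a3, a collagen chain, fell by 1.32 ± 0.182 (adjusted p = 0.0202) and was chosen after its values were seen.

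Canonical interferon-stimulated genes were abundant before treatment. Isg15, a ubiquitin-like modifier, stood at 2914 ± 395 FPKM in the untreated wild type, rank 20 of all genes, and at 3261 ± 493 with IFNα (0.15 ± 0.161, adjusted p = 1). The median percentile of the 58 antiviral interferon-stimulated genes among the genes tested was 82.7, and 33 of them lay at 10 FPKM or above. With IFNα 0 of the 58 passed in edgeR over all genes, and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 13, and DESeq2 and limma each called 0. Their median log2 fold change was 0.09 (camera adjusted p = 0.127). The upper 95% limit lay under 2-fold for 55 of the 58, and the largest value was 0.64, in Apobec3, a cytidine deaminase chosen after its values were seen. The log2 fold change was 0.30 ± 0.131 for Stat2, 0.37 ± 0.158 for Rsad2 and 0.36 ± 0.141 for Mx1. It was 0.18 ± 0.157 for Ifit1, −0.28 ± 0.125 for Oas1a, −0.04 ± 0.147 for Usp18 and −0.05 ± 0.103 for Irf9, and the smallest adjusted p of these genes was 0.815. Reads can be shared between near-identical members of the Oas1 and Ifit families, so the values of Oas1a and Ifit1 are uncertain.

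Of 3 interferon genes tested in the wild type 0 passed over all genes and 2 were higher adjusted over the list alone (2 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). Ifnb1 lay at 15.9 ± 2.28 and 26.9 ± 3.61 FPKM without and with IFNα (0.75 ± 0.165, adjusted p = 0.361), and Ifna4 had a log2 fold change of 1.5 ± 0.369 (adjusted p = 0.441). The chemokine and cytokine list moved up (camera adjusted p = 0.0111; adjusted p = 0.236 with an estimated correlation). Of its 32 members 0 passed over all genes and 1, Cxcl10, was higher adjusted over the list alone (6 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). The value for Cxcl10, a T-cell attractant, was 0.48 ± 0.117 (adjusted p = 0.441) and that for Ccl5 −0.12 ± 0.148 (adjusted p = 1). Interferon-inducible GTPases moved up (median 0.23, camera adjusted p = 0.000604; adjusted p = 0.716 with an estimated correlation). Among its members 0 of 17 passed, also adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2 and limma). Of 12 interferon regulatory factors 1, Irf1, rose, also adjusted over the list alone, and 11 did not pass. The chemokine call was lost without wild-type control 3 (camera adjusted p = 0.176) or wild-type IFNα 2 (camera adjusted p = 0.067). The chemokine list moved with the lung transcripts, present in 3 of 3 IFNα and 1 of 3 control libraries of the wild type, and its median of 0.36 was 0.21 in unscaled FPKM and 0.14 after quantile normalization.

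The cell cycle list moved up in IFNα-treated wild-type cells (median 0.25, camera adjusted p = 9.17e-10; adjusted p = 0.251 with an estimated correlation). Of its 44 members 0 passed, also adjusted over the list alone, with 12 at an unadjusted p under 0.05 and 0 by DESeq2 and limma. Tpx2, a spindle factor, was at 0.35 and the kinase Aurkb at 0.38. The pigmentation list moved down (camera adjusted p = 0.00827; adjusted p = 0.716 with an estimated correlation), with a median of −0.10 but a mean of 0.11. Of its members 0 of 28 passed, also adjusted over the list alone (7 at an unadjusted p under 0.05, 0 by DESeq2 and limma). MHC class I presentation genes moved down (camera adjusted p = 0.0199; adjusted p = 0.716 with an estimated correlation), at a median of −0.03 (−0.05 in unscaled FPKM, −0.10 after quantile normalization) but a mean of 0.04. Over all genes 0 of 25 passed, and 3 were lower adjusted over the list alone (8 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). These were Psme1 at −0.45, H2-T23 at −0.47 and H2-T22 at −0.36. The log2 fold change was −0.26 ± 0.113 for H2-K1, −0.23 ± 0.165 for B2m, 0.27 ± 0.113 for Tap1, 0.43 ± 0.194 for Nlrc5 and 0.40 ± 0.156 for Cd274, which encodes PD-L1. The smallest adjusted p of these genes was 0.815. The class I call was lost without wild-type control 1, wild-type control 3 or wild-type IFNα 2, at a camera adjusted p = 0.0712, 0.112 and 0.192, and with the length trend removed, at 0.0796. That of pigmentation was lost without wild-type control 3, wild-type IFNα 2 or wild-type IFNα 3, at 0.0983, 0.067 and 0.0715.

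Cholesterol biosynthesis genes (median 0.13) and collagens (median 0.28) moved up, each at a camera adjusted p = 0.0199 and an adjusted p = 0.716 with an estimated correlation. By edgeR 0 of 25 and 0 of 32 passed, also adjusted over the list alone (5 and 8 at an unadjusted p under 0.05, 0 by DESeq2 and limma). Without wild-type control 1 or wild-type IFNα 1 the cholesterol call was lost (camera adjusted p = 0.284 and 0.298). The collagen call was lost without wild-type control 1, wild-type control 2, wild-type IFNα 1 or mutant IFNα 1 (0.0772, 0.0842, 0.584 and 0.054), and with the length trend removed (0.0796). The collagens camera used are long, at a median of 6.7 kb against 3.61 kb over all its genes, and long genes were higher (Spearman correlation of 0.149 with length over 5409 genes). The cell cycle and cholesterol lists are long too, at medians of 4.44 and 4.62 kb, and passed with the length trend removed (camera adjusted p = 3.72e-09 and 0.0307). The collagen median was 0.14 in unscaled FPKM and 0.11 after quantile normalization. The collagens moved with the lung transcripts, present in 3 of 3 IFNα and 1 of 3 control libraries of the wild type. Mitf and Tyr, of the melanocyte lineage, were at −0.03 ± 0.133 and 0.05 ± 0.143, and Mki67, a proliferation marker, at 0.09 ± 0.193, each with an adjusted p = 1.

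In all, 4 of 17590 genes passed in the wild type, 1 higher and 3 lower, 3 of them at least 2-fold, and DESeq2 called 65. With library totals as scaling 3 passed, 0 higher and 3 lower. The count was 0 without wild-type IFNα 3, 1 without wild-type control 2, 2 without wild-type control 1, wild-type control 3 or wild-type IFNα 1, and 7 without mutant IFNα 3. Id1 missed the threshold without wild-type IFNα 3, at −1.14, and Id3 without that library or wild-type control 2, at −1.02 and −0.95. Irf1 passed in 4 of the 12 fits that each left out 1 library, and missed it, at 0.64 to 0.73, without any of the 6 wild-type libraries, mutant control 3 or mutant IFNα 1. With a term for the libraries that held lung transcripts 1 gene passed, Id1.

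**Figure D2:**
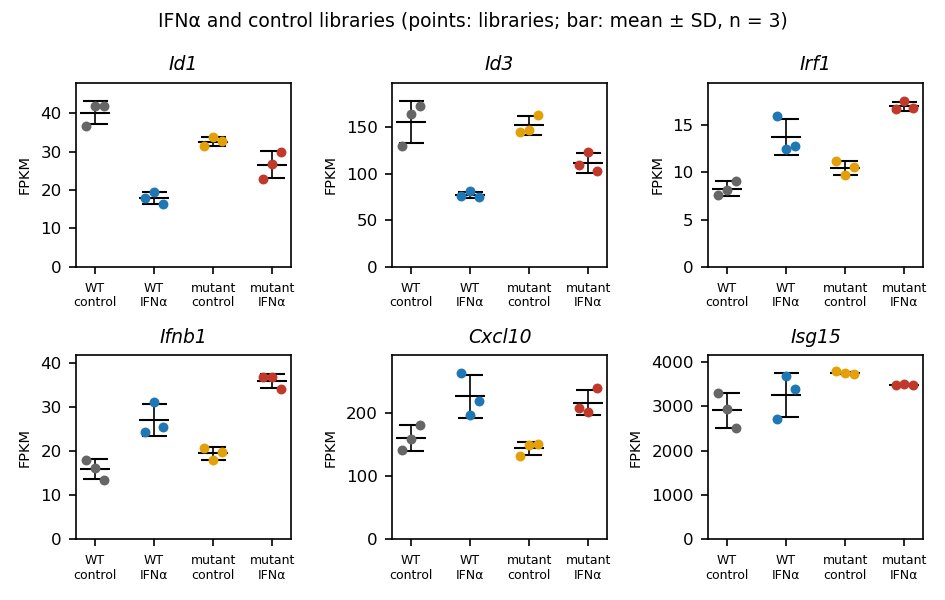
FPKM (linear axis from 0) of Id1, Id3, Irf1, Ifnb1, Cxcl10 and Isg15 in each library, with points for libraries and bars for mean ± SD over n = 3. Id1 lies at 40.1 ± 3 in wild-type controls and 17.9 ± 1.5 in wild-type IFNα, and Isg15 lies at 2914 ± 395 in the untreated wild type.

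IFNα treatment of mutant cells is the same question in the C435A line. It raised H2-K2 (chromosome 17, 34193608 to 34197811), a class I histocompatibility gene, from 9.99 ± 1.41 to 22.2 ± 2.21 FPKM, by 1.13 ± 0.145 (adjusted p = 0.0329, higher in 3 of 3 libraries). Reads of H2-K2 may be shared with its close copy H2-K1 (0.04 ± 0.113, adjusted p = 0.938), so its value is uncertain. Irf1 lay at 10.5 ± 0.756 and 17 ± 0.477 FPKM without and with IFNα, a difference of 0.68 ± 0.0982 that did not pass (adjusted p = 0.0655). Ifnb1 lay at 19.5 ± 1.47 and 35.9 ± 1.59 FPKM (0.85 ± 0.165, adjusted p = 0.162). Ifna4 was at 2.61 ± 0.403 (adjusted p = 0.0864), Cxcl10 at 0.57 ± 0.117 (adjusted p = 0.189), Id1 at −0.32 ± 0.123 (adjusted p = 0.427) and Id3 at −0.47 ± 0.12 (adjusted p = 0.282).

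The antiviral interferon-stimulated genes moved up as a list in the mutant (median 0.17, camera adjusted p = 0.000329; adjusted p = 0.493 with an estimated correlation). Over all genes 0 of the 58 passed in edgeR, and 5 were higher adjusted over the list alone (15 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma). The upper 95% limit lay under 2-fold for 57 of them, and the largest value was 0.62, in Cmpk2, a mitochondrial nucleotide kinase. Isg15 was at −0.13 ± 0.161, Mx1 at 0.37 ± 0.141, Rsad2 at 0.17 ± 0.158 and Ifit1 at 0.12 ± 0.158, with a smallest adjusted p of 0.427. Nucleic acid sensing genes moved up (median 0.15, camera adjusted p = 0.00204; adjusted p = 0.493 with an estimated correlation). Over all genes 0 of 36 passed and 6 were higher adjusted over the list alone (7 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma). They included Mndal at 0.72 and Ifi204 at 0.70, members of the AIM2-like DNA sensor family with close copies, whose values are uncertain for that reason. These lists were called in each fit without 1 library, among them that without mutant IFNα 3, the library that stood apart. Long genes were higher in this comparison, at a Spearman correlation of 0.231 with length over 5409 genes, and the lists are long, at medians of 4.28 and 4.49 kb against 3.61 kb over the genes camera used. Both moved up with the length trend removed as well (camera adjusted p = 0.0002 and 0.0124).

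The JAK-STAT list moved up (camera adjusted p = 0.0253; adjusted p = 0.669 with an estimated correlation), as did interferon-inducible GTPases (camera adjusted p = 0.00579; adjusted p = 0.529 with an estimated correlation) and NF-kB targets (camera adjusted p = 0.027; adjusted p = 0.527 with an estimated correlation). Interferon regulatory factors moved up at a median of 0.12 but a mean of −0.10 (camera adjusted p = 0.0057; adjusted p = 0.493 with an estimated correlation). Of the 25, 17, 27 and 12 members of these lists 0 passed over all genes, and 1, 0, 2 and 1 were higher adjusted over the list alone. At an unadjusted p under 0.05 there were 6, 3, 6 and 3, and DESeq2 called 1, 0, 2 and 1 and limma 0. The JAK-STAT call was lost without mutant control 1 or mutant IFNα 2 (camera adjusted p = 0.0535 and 0.0822) and, with members of a median 5.7 kb, with the length trend removed (0.0566). That of the GTPases was lost without mutant control 2 or mutant IFNα 2 (0.0637 and 0.0808), and that of NF-kB targets without mutant control 1 or mutant IFNα 3 (0.0605 and 0.152).

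Ribosomal protein genes moved down in IFNα-treated mutant cells (median −0.21, −0.12 after quantile normalization; camera adjusted p = 1.22e-06; adjusted p = 0.514 with an estimated correlation). They are short, at a median transcript length of 1.88 kb against 3.12 kb over 5409 genes, and over those genes the log2 fold change had a Spearman correlation of 0.231 with length, so that short genes were lower. Of these 0 of 42 passed, also adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2 and limma). The cell cycle list moved up (median 0.20, camera adjusted p = 0.000466; adjusted p = 0.493 with an estimated correlation). Its genes are long, at a median of 4.44 kb, and it passed with the length trend removed (camera adjusted p = 0.00342), as did the ribosomal list (7.26e-05). Among its members 0 of 44 passed and 1, the transcription factor E2f1 (0.68), was higher adjusted over the list alone (11 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). Pigmentation genes moved down (camera adjusted p = 0.0253; adjusted p = 0.708 with an estimated correlation), with 0 of 28 past the threshold and 2, Trpm1 (−0.43) and S100b (−0.60), lower adjusted over the list alone (6 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). The integrated stress list (camera adjusted p = 0.0253; adjusted p = 0.708 with an estimated correlation) and immediate-early genes (camera adjusted p = 0.0369; adjusted p = 0.669 with an estimated correlation) moved up. Over all genes 0 of 33 and 0 of 30 passed, with 5 and 1 higher and 1 and 0 lower adjusted over the list alone (10 and 4 at an unadjusted p under 0.05, 2 and 1 by DESeq2, 0 by limma). Leukocyte markers moved down (median −0.35, camera adjusted p = 0.00179; adjusted p = 0.493 with an estimated correlation), with 0 of 22 past the threshold and 2 lower adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2 and limma). They moved with the lung transcripts, present in 1 of 3 IFNα and 3 of 3 control libraries of the mutant, and their call was lost without mutant IFNα 2 (camera adjusted p = 0.111). They are short as well, at a median of 1.38 kb, and passed with the length trend removed (camera adjusted p = 0.0124). Pigmentation was lost without mutant control 1, mutant IFNα 1 or mutant IFNα 2 (0.0501, 0.0742 and 0.0808), integrated stress without mutant control 3 or mutant IFNα 2 (0.104 and 0.171), and immediate-early genes without mutant control 3, mutant IFNα 2 or mutant IFNα 3 (0.104, 0.0689 and 0.0769).

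In the mutant 1 of 17590 genes passed, while DESeq2 called 145 and limma 3. The count was 0 without mutant control 1 or 2, mutant IFNα 1 or 2, or wild-type IFNα 1 or 2, and 2 without wild-type control 1, wild-type IFNα 3 or mutant IFNα 3. H2-K2 was among those 2 except without mutant IFNα 3, where it was at 1.03, and it missed the threshold with the term for lung transcripts, at 1.21.

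Mutant against wild-type cells without IFNα asks what the C435A line expressed at rest. The substitution and any other difference between the lines cannot be told apart in the mutant comparisons. Pycard (chromosome 7, 127588880 to 127593039), which encodes the inflammasome adaptor ASC, fell from 7.06 ± 1.03 to 0.418 ± 0.0352 FPKM, and on the log2 scale it fell by 3.98 ± 0.298 (adjusted p = 1.94e-05). Mbp, myelin basic protein, fell from 45 ± 7.41 to 11.5 ± 0.346 FPKM, a change of −1.87 ± 0.124 (adjusted p = 7.87e-06). Nqo1 (chromosome 8, 108114857 to 108129838), a quinone reductase of the antioxidant response, rose from 0.748 ± 0.31 to 6.82 ± 0.992 FPKM, by 3.27 ± 0.34 (adjusted p = 0.00043). Fabp3, a fatty acid binding protein, rose from 12.9 ± 2.05 to 42.3 ± 6.83 FPKM, by 1.81 ± 0.153 (adjusted p = 5.19e-05). For these genes and the largest changes that follow, every mutant library lay beyond every wild-type library.

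Among the other genes that rose were Batf, an AP-1 family transcription factor (1.36 ± 0.177, adjusted p = 0.00385), Tmsb10, an actin-binding thymosin (0.92 ± 0.154, adjusted p = 0.026), and Neurl3, a ubiquitin ligase (0.91 ± 0.142, adjusted p = 0.0195). Apod, a lipid-carrying lipocalin (0.74 ± 0.125, adjusted p = 0.0297), and Isg20, an interferon-induced exonuclease (0.59 ± 0.107, adjusted p = 0.044), also rose. Besides Irf7, Vac14, a scaffold of the PIKfyve lipid kinase complex (−1.03 ± 0.141, adjusted p = 0.0057), and Bfsp2, an intermediate filament protein (−0.92 ± 0.108, adjusted p = 0.00129), fell. So did Clu, a secreted chaperone (−0.74 ± 0.12, adjusted p = 0.0231), and Chn2, a GTPase-activating protein for Rac (−0.72 ± 0.119, adjusted p = 0.0255). Nqo1, Fabp3, Batf, Pycard, Mbp and Bfsp2 passed in all 12 fits that each left out 1 library. Vac14 missed the threshold without mutant control 1 or 3, at −0.97 and −1.04. Tmsb10 (0.81 to 0.99) and Chn2 (−0.77 to −0.64) missed it without any of the 6 control libraries, Neurl3 (0.74 to 1.04) without any but mutant control 1 and Clu (−0.79 to −0.68) without any but wild-type control 1. Apod (0.66 to 0.84) missed it without any control library but mutant control 2, and without wild-type IFNα 2, and Isg20 (0.53 to 0.69) passed only without wild-type control 1 or mutant IFNα 3. With the term for lung transcripts Apod, Isg20, Clu and Chn2 missed it, at 0.69, 0.55, −0.74 and −0.77.

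**Figure D3:**
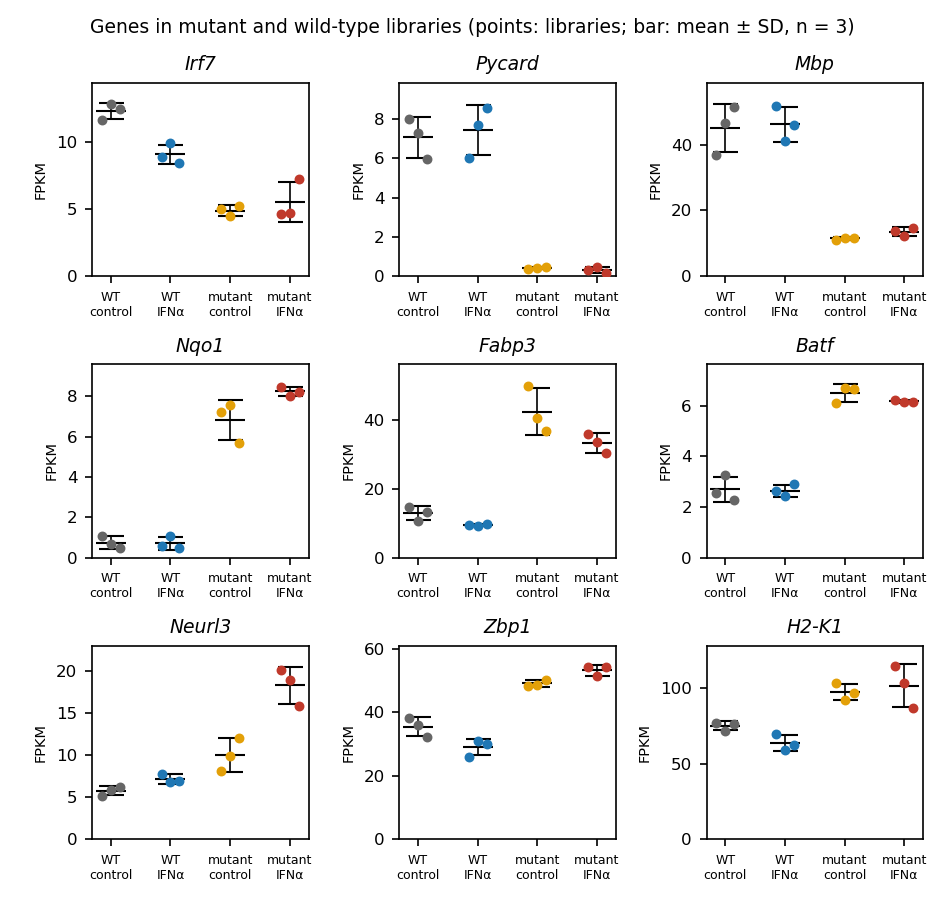
FPKM (linear axis from 0) of Irf7, Pycard, Mbp, Nqo1, Fabp3, Batf, Neurl3, Zbp1 and H2-K1 in each library, with points for libraries and bars for mean ± SD over n = 3. Pycard lies at 7.06 ± 1.03 in wild-type and 0.418 ± 0.0352 in mutant controls, and Nqo1 at 0.748 ± 0.31 and 6.82 ± 0.992.

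The antiviral interferon-stimulated genes moved up in the mutant controls (camera adjusted p = 0.0269; adjusted p = 0.684 with an estimated correlation), with a median of 0.10 that became −0.01 in unscaled FPKM. Of 58 members 1, Isg20, rose and 57 did not pass. Adjusted over the list alone 7 were higher, among them Mx2 (0.61, adjusted p = 0.105) and Zbp1, a sensor of Z-form nucleic acids (0.56, adjusted p = 0.136). Isg15 was at 0.45 ± 0.161 (adjusted p = 0.348) and Mx1 at 0.59 ± 0.142 (adjusted p = 0.139). The 3 interferon genes tested had 0 past the threshold in edgeR (2 at an unadjusted p under 0.05, 1 lower by DESeq2, 1 by limma). Their median was −0.46, and −0.41 in unscaled FPKM. Mx1, Mx2 and Apod lie on chromosome 16, whose 382 genes with an average above 1 CPM had a median 0.24 above that of the other chromosomes. Nucleic acid sensing genes moved down as a list (camera adjusted p = 0.0251; adjusted p = 0.647 with an estimated correlation), at a median of −0.12 but a mean of 0.01. Of 36 members 1, Irf7, fell and 35 did not pass, while Aim2, a cytosolic DNA sensor, and Irak2 (2 in all) were higher and Irf7 (1) lower adjusted over the list alone. Chemokines and cytokines moved up (median 0.38, camera adjusted p = 0.000338; adjusted p = 0.0627 with an estimated correlation). By edgeR 0 of 32 passed and 2, Ccl5 (0.56 ± 0.148, adjusted p = 0.197) and Cxcl2 (0.78, adjusted p = 0.212), were higher adjusted over the list alone (8 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). The chemokine list moved with the lung transcripts, present in 3 of 3 mutant and 1 of 3 wild-type controls. Its genes are short, at a median of 1.84 kb against 3.61 kb over the genes camera used, and short genes were higher (Spearman correlation of −0.368 with length over 5409 genes). With the length trend removed its camera adjusted p was 0.0281. Of 25 MHC class I genes 0 passed and 4, H2-K1 (0.47 ± 0.113, adjusted p = 0.138) among them, were higher adjusted over the list alone (9 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). Without wild-type control 1, wild-type control 2 or mutant control 3 the call of the antiviral list was lost (camera adjusted p = 0.0828, 0.0506 and 0.0704), and without wild-type control 1 that of nucleic acid sensing (0.0828). The sensing genes are long, at a median of 4.49 kb, and their call was lost with the length trend removed (camera adjusted p = 0.165). The median of the sensing list was −0.21 with library totals and −0.19 in unscaled FPKM. The class I list did not pass (camera adjusted p = 0.138) except with the length trend removed (0.0478), and its median of 0.28 became −0.01 in unscaled FPKM and −0.07 after quantile normalization.

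Ribosomal protein genes moved up in the mutant controls (median 0.32, 0.15 after quantile normalization; camera adjusted p = 2.41e-13; adjusted p = 0.427 with an estimated correlation). The log2 fold change had a Spearman correlation of −0.368 with transcript length over 5409 genes, so that short genes, as ribosomal protein genes are, were higher, and with the length trend removed the list passed at a camera adjusted p = 1.28e-09. Over all genes 0 of 42 passed, also adjusted over the list alone (15 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). Pigmentation genes moved down (median −0.17, camera adjusted p = 2.84e-05; adjusted p = 0.499 with an estimated correlation). Of these 0 of 28 passed and 1, the melanocortin receptor Mc1r (−0.48, adjusted p = 0.169), was lower adjusted over the list alone (10 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). Cholesterol biosynthesis genes (median −0.21, camera adjusted p = 0.000338; adjusted p = 0.499 with an estimated correlation) and cell cycle genes (median −0.11, camera adjusted p = 0.0393; adjusted p = 0.684 with an estimated correlation) moved down. Both lists are long, at medians of 4.62 and 4.44 kb against 3.61 kb over the genes camera used. With the length trend removed the cholesterol call held (camera adjusted p = 0.000702) and the cell cycle call was lost (0.133). In these lists 0 of 25 and 0 of 44 passed, also adjusted over the list alone (6 and 3 at an unadjusted p under 0.05, 1 and 0 by DESeq2, 0 by limma). Leukocyte markers moved up (median 0.52, camera adjusted p = 3.9e-07; adjusted p = 0.0891 with an estimated correlation), with 0 of 22 past the threshold, also adjusted over the list alone (8 at an unadjusted p under 0.05, 0 by DESeq2 and limma). They moved with the lung transcripts, present in 3 of 3 mutant and 1 of 3 wild-type controls, and their median was 0.32 in unscaled FPKM. They are short, at a median of 1.38 kb, and passed with the length trend removed (camera adjusted p = 2.28e-05). The median of the pigmentation genes was −0.27 with library totals, −0.28 in unscaled FPKM and −0.27 after quantile normalization, and that of the cell cycle genes −0.22 with library totals and −0.18 in unscaled FPKM. The cell cycle call was lost without wild-type control 1, wild-type control 3, mutant control 1 or mutant control 2 (camera adjusted p = 0.112, 0.11, 0.0613 and 0.0514).

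At rest 29 of 17590 genes passed, 15 higher and 14 lower, 22 of them at least 2-fold, and DESeq2 called 240. The higher share of 51.7% was 40% with library totals as scaling, 68.4% after quantile normalization and 28.6% without wild-type control 2 (4 higher and 10 lower). The count fell to 14 without wild-type control 2, mutant control 1 or mutant control 2, to 17 without wild-type control 3 and to 11 without mutant control 3, and was 58 without mutant IFNα 3.

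Mutant against wild-type cells with IFNα asks the same of treated cells. Pycard fell from 7.42 ± 1.28 to 0.315 ± 0.154 FPKM, a change of −4.47 ± 0.305 (adjusted p = 1.16e-05), and Mbp changed by −1.67 ± 0.123 (adjusted p = 1.55e-05). Nqo1 rose from 0.707 ± 0.332 to 8.25 ± 0.227 FPKM, by 3.62 ± 0.344 (adjusted p = 0.00017), Fabp3 by 1.9 ± 0.154 (adjusted p = 3.82e-05) and Neurl3 by 1.45 ± 0.143 (adjusted p = 0.000225). H2-K2 rose by 1.40 ± 0.146 (adjusted p = 0.000392). Genes of antigen presentation and antiviral defence also rose, H2-K1 by 0.77 ± 0.114 (adjusted p = 0.00758), Oasl1 by 1.05 ± 0.153 (adjusted p = 0.00722) and Zbp1 by 0.96 ± 0.133 (adjusted p = 0.00545). Reads may be shared between H2-K1 and H2-K2, so both values are uncertain.

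Further genes that rose were Batf (1.31 ± 0.177, adjusted p = 0.00486), Cort, which encodes the neuropeptide cortistatin (1.20 ± 0.211, adjusted p = 0.0219), Acsbg1, an acyl-CoA synthetase (1.09 ± 0.147, adjusted p = 0.00486), and Hrct1 (0.88 ± 0.178, adjusted p = 0.0405). Those that fell were the glutathione transferases Mgst1 (−1.16 ± 0.192, adjusted p = 0.0163) and Gsta2 (−0.89 ± 0.174, adjusted p = 0.0351), Vac14 (−0.73 ± 0.14, adjusted p = 0.0321), Clu (−0.72 ± 0.119, adjusted p = 0.0163) and Bfsp2 (−0.65 ± 0.107, adjusted p = 0.0163). Gsta2 has near-identical family members, so its value is uncertain. Nqo1, Fabp3, Neurl3, H2-K2, Batf, Acsbg1, Zbp1, Pycard and Mbp passed in all 12 fits that each left out 1 library. Oasl1 missed the threshold without wild-type IFNα 1 or 2 (1.01 and 1.03), H2-K1 without wild-type IFNα 2 or 3 (0.67 to 0.86 over the 12 fits) and Bfsp2 without wild-type IFNα 2 or 3 (−0.62 and −0.65). Mgst1 missed it without wild-type IFNα 2 or 3 or mutant IFNα 2 (−1.31 to −1.02), Clu without wild-type IFNα 1 or 3 or mutant IFNα 2 (−0.79 to −0.60) and Cort without any IFNα library but mutant IFNα 3 (1.07 to 1.29). Hrct1 (0.73 to 0.99) passed only without wild-type control 1 or mutant IFNα 1, Gsta2 (−0.97 to −0.77) only without wild-type control 1 or 3, and Vac14 (−0.89 to −0.65) only without wild-type control 1, wild-type control 3 or mutant IFNα 3. With the term for lung transcripts Cort, Hrct1, Mgst1, Gsta2, Vac14 and Clu missed it, at 1.21, 0.96, −1.08, −0.89, −0.70 and −0.72.

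MHC class I presentation genes moved up with IFNα (median 0.35, camera adjusted p = 5.82e-05; adjusted p = 0.462 with an estimated correlation). Of 25 members 4 rose and 21 did not pass, and 11 were higher and 3 lower adjusted over the list alone. The 4 were H2-K1, H2-T22 (0.76 ± 0.108, adjusted p = 0.00625), H2-T23 (0.64 ± 0.121, adjusted p = 0.0294) and the immunoproteasome subunit Psmb10 (0.50 ± 0.0945, adjusted p = 0.0308). H2-T22 has a close relative in H2-T10, so its value is uncertain. B2m, the class I light chain, was at 0.35 ± 0.165 (adjusted p = 0.365), Tap1 at 0.37 ± 0.113 (adjusted p = 0.159) and Nlrc5 at −0.20 ± 0.193 (adjusted p = 0.701). The antiviral interferon-stimulated genes moved up (median 0.12, but 0.04 with library totals and 0.03 in unscaled FPKM; camera adjusted p = 5.82e-05; adjusted p = 0.462 with an estimated correlation), with 5 of 58 higher, 53 not past the threshold and 14 higher adjusted over the list alone. The 5 were Zbp1, Oasl1, Isg20 (0.77 ± 0.108, adjusted p = 0.00545), Oas1b (0.68 ± 0.105, adjusted p = 0.0114), uncertain for its near copies, and Mx2 (0.68 ± 0.131, adjusted p = 0.0321), chosen after its values were seen. H2-T22 and Isg20 passed in all 12 fits that each left out 1 library, Oas1b missed the threshold without any of the wild-type IFNα libraries (0.63 to 0.74), and H2-T23 (0.58 to 0.72) and Psmb10 (0.48 to 0.51) passed in 4. H2-T23 missed it without wild-type control 2, mutant control 1 or 3, or any IFNα library but mutant IFNα 3, and Psmb10 without any mutant control or any IFNα library but mutant IFNα 3. With the term for lung transcripts Oas1b, H2-T23 and Psmb10 missed it, at 0.62, 0.56 and 0.48. Isg15 was at 0.18 ± 0.161 (adjusted p = 0.686), Mx1 at 0.60 ± 0.142 (adjusted p = 0.0745) and Ifnb1 at 0.50 ± 0.163 (adjusted p = 0.194).

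The chemokine and cytokine list moved up (median 0.13, camera adjusted p = 0.0125; adjusted p = 0.329 with an estimated correlation). Among its members 0 of 32 passed and 1, Ccl5 (0.62 ± 0.149, adjusted p = 0.0772), was higher adjusted over the list alone (5 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). NF-kB targets moved up (median 0.21, camera adjusted p = 0.0112; adjusted p = 0.462 with an estimated correlation), with 0 of 27 past the threshold and 2, Nfkbie and Relb, higher adjusted over the list alone (7 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma). MHC class II genes moved up (median 0.19, camera adjusted p = 0.049; adjusted p = 0.462 with an estimated correlation), with 0 of 13 past the threshold and 2, Cd74 and H2-Oa, higher adjusted over the list alone (4 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). In 5 further lists 1 member each rose over all genes. These were the GTPase Tgtp1 (0.80 ± 0.14, adjusted p = 0.0207), whose near-identical copy makes its value uncertain, Aim2 (1.70 ± 0.35, adjusted p = 0.0444), the aldolase Aldoc (0.81, adjusted p = 0.0207), Junb (0.55, adjusted p = 0.0371) and Ppp1r15a (0.53, adjusted p = 0.044). Adjusted over the list alone those lists, of 17, 36, 36, 30 and 33 members, had 1, 4, 1, 3 and 7 higher and 0, 2, 0, 0 and 2 lower, and none of them passed camera (adjusted p = 0.457, 0.407, 0.672, 0.116 and 0.319). Tgtp1 and Aldoc missed the threshold without any IFNα library but mutant IFNα 3 (0.74 to 0.88 and 0.73 to 0.86), and Junb (0.48 to 0.61) without any mutant control or any IFNα library. Aim2 (1.51 to 1.94) passed only without wild-type control 1 or mutant IFNα 3 and Ppp1r15a (0.45 to 0.58) only without wild-type control 1. With the term for lung transcripts Aim2, Aldoc, Junb and Ppp1r15a missed it, at 0.96, 0.74, 0.48 and 0.45. With library totals the medians of chemokines, NF-kB targets and class II genes were 0.06, 0.13 and 0.10, and that of NF-kB targets was 0.07 in unscaled FPKM. The chemokine call was lost without wild-type IFNα 1 or mutant IFNα 3 (camera adjusted p = 0.0828 and 0.0764), and that of NF-kB targets without mutant IFNα 3 (0.132). That of class II was lost without wild-type control 1 or 3, mutant control 3, wild-type IFNα 1 or 3, or mutant IFNα 1 or 3 (0.0517 to 0.121). The chemokine and class II genes camera used are short, at medians of 1.84 and 1.76 kb against 3.61 kb, short genes were higher (Spearman correlation of −0.226 with length over 5409 genes), and with the length trend removed both calls were lost, each at a camera adjusted p = 0.177.

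Pigmentation genes moved down (median −0.23, camera adjusted p = 0.000108; adjusted p = 0.462 with an estimated correlation). By edgeR 0 of 28 passed and 4 were lower adjusted over the list alone (10 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma). The 4 were Trpm1 (−0.40), S100b (−0.58), Tyr, which encodes tyrosinase (−0.46 ± 0.143, adjusted p = 0.17), and Mitf, a melanocyte transcription factor (−0.42 ± 0.133, adjusted p = 0.172). Cholesterol biosynthesis genes moved down (median −0.20, camera adjusted p = 0.000774; adjusted p = 0.462 with an estimated correlation). In edgeR 0 of 25 passed and 4, Sqle (−0.55), Hmgcs1 (−0.81), Idi1 (−0.73) and Msmo1 (−0.58), were lower adjusted over the list alone (8 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma). Cell cycle genes moved down (median −0.17, camera adjusted p = 0.00541; adjusted p = 0.47 with an estimated correlation), with 0 of 44 past the threshold, also adjusted over the list alone (9 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma). Ribosomal protein genes moved up (median 0.09, camera adjusted p = 0.0382; adjusted p = 0.843 with an estimated correlation), a median that became 0.03 with library totals, 0.01 in unscaled FPKM and −0.04 after quantile normalization. The Spearman correlation of the log2 fold change with transcript length was −0.226, so that short genes were higher. The ribosomal call was lost without wild-type IFNα 1, mutant IFNα 1 or mutant IFNα 2 (camera adjusted p = 0.763, 0.281 and 0.345), and with the length trend removed (0.349). The cholesterol and cell cycle lists are long, at medians of 4.62 and 4.44 kb against 3.61 kb over the genes camera used, and passed with it removed (0.000506 and 0.0119). Of 42 members 1, Rps2 (0.67 ± 0.128, adjusted p = 0.0316), rose, also adjusted over the list alone, and 41 did not pass. Rps2 passed in 3 of the 12 fits that each left out 1 library (only without wild-type control 1, wild-type control 3 or mutant IFNα 3) and missed the threshold with the term for lung transcripts, at 0.57. Rps2 and its copies made up 5 of the 105 genes past the threshold, and their values are uncertain because close copies can share reads. Leukocyte markers moved up (median 0.21, camera adjusted p = 0.0382; adjusted p = 0.462 with an estimated correlation), with 0 of 22 past the threshold, also adjusted over the list alone (3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma). Their median was 0.14 with library totals and 0.13 in unscaled FPKM, and their call was lost without wild-type IFNα 1, mutant IFNα 1 or mutant IFNα 3 (camera adjusted p = 0.371, 0.0914 and 0.317), and with the length trend removed (0.173). The lung transcripts went the other way, present in 1 of 3 mutant and 3 of 3 wild-type IFNα libraries.

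With IFNα 105 of 17590 genes passed, 83 higher and 22 lower, 34 of them at least 2-fold, and DESeq2 called 599 and limma 56. With library totals as scaling 49 passed, and the higher share of 79% was 65.3%. The count was 27, 21 and 24 without wild-type IFNα 1, 2 and 3, 59 and 43 without mutant IFNα 1 and 2, and 63, 66 and 65 without mutant control 1, 2 and 3.

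The interaction asks whether the response to IFNα differed between the lines. Of 17590 genes 0 passed in edgeR, with 909 at an unadjusted p under 0.05 where 880 would be by chance, and limma called 0 and DESeq2 14. The difference in response was 0.86 ± 0.174 for Id1, 0.55 ± 0.169 for Id3, 1 ± 0.204 for H2-K2 and 0.61 ± 0.235 for Irf7, each with an adjusted p = 0.916. Id1, Id3 and H2-K2 were chosen for this comparison after their values were seen. Calls made in a single line are therefore not shown to differ between the lines. For Ifnb1 it was 0.11 ± 0.232, for Isg15 −0.28 ± 0.228 and for Cxcl10 0.09 ± 0.165, with a smallest adjusted p of 0.918. In simulated data for this comparison, differences of 4-fold were recovered in 45.5% of 66 genes and of 2-fold in 9% of 67.

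Nucleic acid sensing genes had a higher response in the mutant as a list (median 0.17, camera adjusted p = 0.00186; adjusted p = 0.904 with an estimated correlation). So did MHC class I genes, at a median of 0.13 but a mean of −0.11 (camera adjusted p = 0.0126; adjusted p = 0.904 with an estimated correlation). Ribosomal protein genes had a lower one (median −0.25, camera adjusted p = 9.6e-05; adjusted p = 0.904 with an estimated correlation). With edgeR 0 of 36, 0 of 25 and 0 of 42 members passed, also adjusted over the list alone (7, 4 and 0 at an unadjusted p under 0.05, 0 by DESeq2 and limma). The class I call was lost without mutant control 2, mutant IFNα 1 or mutant IFNα 2 (camera adjusted p = 0.0927, 0.0762 and 0.169) and the ribosomal call without wild-type control 3 (0.0764). Short genes were lower over the 5409 genes, at a Spearman correlation of 0.105 with length, and with that trend removed the sensing, class I and ribosomal lists passed (camera adjusted p = 0.00457, 0.0296 and 0.000161). Of 58 antiviral interferon-stimulated genes 0 passed, also adjusted over the list alone (5 at an unadjusted p under 0.05, 0 by DESeq2 and limma), at a median of 0.07 (camera adjusted p = 0.0779). Of 13 MHC class II genes 0 passed and 2, H2-Eb1 and H2-Ab1, were lower adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2 and limma). This comparison sets the groups in which all libraries held lung transcripts against those in which 1 of 3 did.

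Both mutant comparisons were set side by side across genes. Over the 114 genes past the threshold in either, the log2 fold changes of both comparisons, which share no library, had a Pearson correlation of 0.834, and 98.2% had the same direction. The correlation was 0.34 without mutant control 3 and 0.251 without mutant IFNα 3. Over all 17590 genes the correlation was 0.041 and the share 61.1%, so the first values describe genes picked for their size. Both comparisons called 20 genes, where independent lists would share 0.17, 9 higher and 11 lower in both. The count was 10 without wild-type control 2 or 3, mutant control 1 or wild-type IFNα 3, 9 without mutant control 3 or wild-type IFNα 2, 11 and 13 without mutant control 2 and mutant IFNα 2, and 32 without mutant IFNα 3. Nqo1, Fabp3, Batf, Neurl3, Apod and Isg20 were among the higher and Pycard, Mbp, Vac14, Bfsp2, Clu and Chn2 among the lower. Both comparisons set the same mutant line against the same wild-type line, so any lasting difference between the lines recurs in both. The 0.17 is therefore no measure for an effect of the substitution, which cannot be told apart from other differences between the lines. The IFNα response had a Pearson correlation of 0.896 and a slope of 0.564, mutant on wild type, over the 5 genes past the threshold in either line. The correlation was 0.468 without wild-type IFNα 2 and 0.335 without mutant IFNα 3, and the slope was 0.931, 0.359, 0.177 and 0.302 without wild-type control 1, wild-type control 3, mutant control 3 and wild-type IFNα 2. Without wild-type control 2, wild-type IFNα 1 or wild-type IFNα 3 too few genes passed to give either. Over all genes both turned, to −0.081 and −0.094, and over the 58 antiviral interferon-stimulated genes they were 0.278 and 0.528. Genes are not independent replicates, and these values carry no p.

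**Figure D4:**
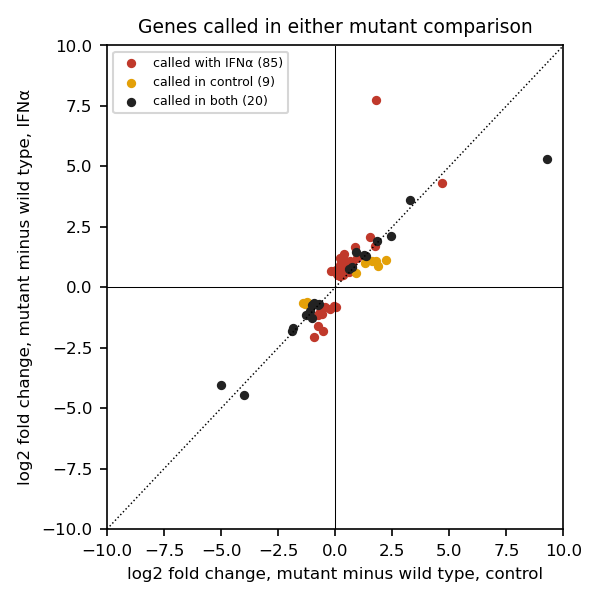
Log2 fold change of mutant against wild type in controls (x axis) and with IFNα (y axis) for the 114 genes past the threshold in either comparison, colored by where they passed, with the line of equal change dotted. Of these, 98.2% have the same direction in both comparisons.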

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

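The tests of the list differences and the other splits of the libraries were set before the data were examined, and the list tests without single libraries and with the length trend removed were chosen after the result was seen. The response to IFNα differed between the lines for 3 gene lists by the camera test of the interaction. MHC class I genes (adjusted p = 0.0126) and nucleic acid sensing genes (adjusted p = 0.00186) had a higher response in the mutant, and ribosomal protein genes (adjusted p = 9.6e-05) a lower one. Each had an adjusted p = 0.904 with an estimated correlation, and 0 of their 25, 36 and 42 members passed in edgeR. With the trend with transcript length removed each passed (adjusted p = 0.0296, 0.00457 and 0.000161). Without mutant control 2, mutant IFNα 1 or mutant IFNα 2 the class I list did not pass (adjusted p = 0.0927, 0.0762 and 0.169), nor did the ribosomal list without wild-type control 3 (adjusted p = 0.0764).

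The libraries were also regrouped in other ways. For the interaction, all 100 splits drawn gave at least the 0 genes of the real one, as any count would, also at 2-fold, and the highest of the others gave 4. For its lists 65 of 100 splits gave at least the real 3, with a highest of 15. Genotype labels were regrouped separately among control and IFNα libraries, so a split can turn the difference between the lines into an interaction. The split with 15 kept the wild-type controls together and exchanged most IFNα libraries. These splits therefore cannot tell how often chance alone gives 3 lists, and chance was not excluded for the list differences. In the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. With IFNα in the wild type the real split gave 4 genes, 3 at 2-fold and 7 lists, and the highest other 0, 0 and 8, and 1, 1 and 3 splits gave as many. With IFNα in the mutant the real one gave 1, 1 and 12 and the highest other 2, 2 and 6, with 5, 5 and 1 splits as high. For the mutant without IFNα it gave 29, 22 and 8 against 3, 3 and 8, with 1, 1 and 2 splits as high, and with IFNα 105, 34 and 10 against 0, 0 and 7, with 1 split as high for each.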

How the results depend on the processing

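The term for lung transcripts, the fit of only the 8 libraries that held them, the FPKM minimum of 1 in edgeR, division of counts by 4, leaving out both libraries with the largest TMM factors, list tests without single libraries, and list tests with the length trend removed were chosen after the data were seen. Values are in the order IFNα in the wild type, IFNα in the mutant, mutant without IFNα, mutant with IFNα, where the reported counts are 4, 1, 29 and 105 (3, 1, 22 and 34 at 2-fold), with 0 in the interaction. Where a count moved by over 1.5 times the cause was not tested, except that fewer libraries or genes entered some fits by construction. The named genes made 627 pairs of gene and comparison, of which a setting could test between 399 (an FPKM minimum of 5) and all. Among those a setting could test, 0 that passed as reported changed direction, and up to 36 that had not passed did, the most in the fit of only the 8 libraries with lung transcripts.

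DESeq2 called 65, 145, 240 and 599 genes and 14 in the interaction (18, 45, 98, 124 and 13 at 2-fold), which included all 4, 1, 29 and 105, and Irf7 in the mutant with IFNα then passed, at −0.61. Limma-trend called 3, 3, 35 and 56, of which 3, 1, 19 and 50 were shared with edgeR, and at 2-fold 1, 2 and 11 with IFNα in the wild type, IFNα in the mutant and the mutant with IFNα. Without a variance trend the moved counts were 3 with IFNα in the mutant and 54 for the mutant with IFNα (1, 2 and 11 at 2-fold). With a pseudocount of 0.1 they were 2, 3 and 59 (1, 2 and 19 at 2-fold) for IFNα in the wild type, IFNα in the mutant and the mutant with IFNα, and the slope of the IFNα response was 1.04. Quantile normalization gave 1 gene at 2-fold with IFNα in the wild type and 16 for the mutant with IFNα. An FPKM minimum of 5 gave 4 genes with IFNα in the mutant and 19 in the mutant controls (2 and 9 at 2-fold, and 16 for the mutant with IFNα). Library totals as scaling gave 2 and 49 for the IFNα response of the mutant and the mutant with IFNα (2 at 2-fold for the first), and robust estimation 3 (2 at 2-fold) for the first. With only the groups compared the moved counts were 2, 0 and 14 for IFNα in the wild type, IFNα in the mutant and the mutant with IFNα (0 and 13 at 2-fold in the mutant response and the mutant with IFNα), where fewer libraries shared the estimate of the spread.

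With the term for lung transcripts 1, 1, 21 and 100 genes passed, of which 1, 0, 14 and 52 were among the reported ones (1 at 2-fold with IFNα in the wild type and 59 for the mutant with IFNα). Only the 8 libraries that held them gave 1135, 16 and 1136 in the mutant response, the mutant controls and the mutant with IFNα, and 47 in the interaction (416, 14, 476 and 47 at 2-fold), but this leaves 1 library in 2 of the groups, assumed to vary like the others. The higher share in the mutant with IFNα was then 45.8% in place of 79%, 76 of the 105 were shared, and with IFNα in the wild type 3 genes passed, of which 0 were among the 4 reported. An FPKM minimum of 1 in edgeR gave 5 and 198 for the mutant response and the mutant with IFNα (2 at 2-fold for the first). Counts divided by 4 gave 47 without and 167 with IFNα in the mutant. Leaving out wild-type IFNα 1 and wild-type control 3 gave 0, 0, 12 and 21 (0, 0, 11 and 14 at 2-fold).

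The replicate number does not pair the libraries. Deviations from the group means correlated at −0.134 to 0.088 in 18 pairs of the same number and −0.166 to 0.225 in 36 of different numbers. With the replicate block 2, 0, 17 and 59 genes passed, of which 2, 0, 16 and 58 were among the reported ones (0 and 22 at 2-fold for the mutant response and the mutant with IFNα), and the block changed no count of lists.

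Over all genes the slope and correlation of the IFNα response between the lines reversed, to −0.094 and −0.081, and the correlation of both mutant comparisons was 0.0409, with 61.1% in the same direction. With an estimated correlation, and with fry, 0 lists passed in each of the 5 comparisons, where the reported counts were 7, 12, 8, 10 and 3. With the trend with transcript length removed they were 5, 11, 9, 7 and 3. Those that then came to pass were class I, NF-kB and mitochondrially encoded genes in the mutant controls (adjusted p = 0.0478, 0.0281 and 0.0478) and the cell death list in the mutant with IFNα (0.0243). Without each library in turn, counts of genes ran over 0 to 7, 0 to 2, 11 to 58 and 21 to 112 and 0 to 0 in the interaction (0 to 4, 0 to 2, 10 to 38, 15 to 36 and 0 to 0 at 2-fold), and counts of lists over 4 to 7, 6 to 12, 5 to 10, 6 to 11 and 2 to 5. The slope of the IFNα response ran from 0.177 to 0.931, its correlation from 0.335 to 0.991, the correlation of the mutant comparisons from 0.251 to 0.939 and their same-direction share from 91.3% to 100%. Irf7 ran from −0.56 to −0.39 with IFNα in the wild type, −0.10 to 0.27 in the mutant, −1.29 to −1.17 in the mutant controls and −0.88 to −0.51 in the mutant with IFNα.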

Other observations

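Of the tests in this part, the 3 on transcripts of other tissues, that of the chromosome 16 shift within lines, and those of precision and exchanged labels for the interferon-stimulated genes were chosen only after the result was seen. For the genes passing in both mutant comparisons, the count still past the threshold was set beforehand, but at 10 of 20 it decided nothing and was replaced by the lowest ratio after a median ratio of 1 had been looked at.

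Genes below the FPKM minimum for naming also differed between the lines, and those given here were chosen after their values were seen. Mgll, which encodes monoacylglycerol lipase, fell from 3.92 ± 0.501 to 0.985 ± 0.144 FPKM in the controls (SD, n = 3), by 1.89 ± 0.16 on the log2 scale (adjusted p = 5.19e-05), and changed by −1.81 ± 0.16 with IFNα (adjusted p = 8.29e-05). Elovl4, a fatty acid elongase, changed by −1.04 ± 0.177 (adjusted p = 0.0298) and −1.27 ± 0.178 (adjusted p = 0.00545). Sv2a, a synaptic vesicle protein, changed by −1.10 ± 0.195 (adjusted p = 0.0363) and −0.97 ± 0.194 (adjusted p = 0.0371), and Adam23 by −1.28 ± 0.211 (adjusted p = 0.0255) and −1.15 ± 0.209 (adjusted p = 0.0247). Syk, a tyrosine kinase of immune receptor signaling, rose by 1.27 ± 0.223 (adjusted p = 0.0363) and 1.32 ± 0.223 (adjusted p = 0.0175). Dpysl3 changed by −1.41 ± 0.151 in the controls (adjusted p = 0.000544) and did not pass with IFNα (−0.66 ± 0.148, adjusted p = 0.0628; interaction adjusted p = 0.916).

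Transcripts of lung and blood were present in 8 of the 12 libraries, and those of stratified epithelium, fat and muscle clearly only in part of these. Over the 8, summed transcripts ran from 0.631 to 40.4 CPM for stratified epithelium, 0.45 to 29.8 for fat and 0.528 to 17.5 for muscle. In the libraries without lung transcripts they were at most 0.127, 0.316 and 0.385. By its definition the pattern did not follow genotype or IFNα, with summed lung transcripts ranging 701-fold within mutant IFNα and 365-fold within the wild-type controls. RNA of other tissues shared by libraries of different groups may be the source of these transcripts. For 8 of 8 libraries the closest in tissue mix was in another group. That is the most there can be, and a share of 0.405 of 10000 permutations of the group labels reached it, so this test could not decide. The 8 libraries formed pairs across groups, each closest to the other, at log2 distances of 0.22 to 1.04. The closest pair, mutant control 2 and wild-type IFNα 3, had 18 and 16.3 CPM of blood, 17.5 and 16.2 of muscle and 40.4 and 38.3 of stratified epithelium transcripts. How RNA came to be shared was not tested. For the 20 genes passing in both mutant comparisons, the ratio of the log2 fold changes with to without the term ran from 0.854 to 1.213 (40 of 40 values in the same direction). With the term 10 of the 20 passed in both, as the median standard error went from 0.168 to 0.207. These transcripts were in more mutant than wild-type controls and fewer mutant than wild-type IFNα libraries, so they would move a gene in opposite directions in the 2 comparisons. All 20 genes went the same way in both, which these transcripts alone would not give. Passing in both thus favored genes little affected by them, so a ratio near 1 was likely from the start and decides nothing. Of calls in a single comparison it says nothing: with the term 14 of the 29 without and 52 of the 105 with IFNα still passed.

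Genes of chromosome 16 were higher in the mutant, with a median 0.24 above that of the other chromosomes without IFNα and 0.21 with it, over 382 genes with an average above 1 CPM, against upward shifts of at most 0.036 and 0.08 for any other chromosome and largest downward ones of −0.034 and −0.105. Length or level bias is argued against, since the shifts were 0.247 and 0.215 after the trends with both were removed, and a few regions are too, since 10 of 10 windows of equal gene number lay above the other chromosomes in both comparisons. A candidate explanation is a difference between the lines over the whole chromosome, such as an extra copy. The shift was at most 0.024 in size in the IFNα comparisons, which stay within a line, and the 6 mutant libraries lay at 0.092 to 0.136 and the 6 wild-type ones at −0.133 to −0.078. Copy number was not measured, so whether it came with the substitution or with the choice of clone stays open.

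Interferon-stimulated genes responded little to IFNα and were abundant without it. Too little precision is argued against, since the upper 95% limit of the fold change lay under 2-fold for at least 55 of the 58 in both lines. As to labels exchanged in single libraries, 0 IFNα libraries lay below a control of their line in both Ifnb1 and Cxcl10. These genes were taken with their values known and passed the threshold in neither line, so this cannot decide the question. A ceiling from high unstimulated levels may contribute, but the Spearman correlation of response with level, taken from the other line, was −0.165 in the mutant and −0.221 in the wild type, between the bounds set beforehand for and against it. Dose and time of treatment are not given in the sources used here.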
